A study of Homo sapiens with 16 samples.

How the data were processed

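Expression was measured on Affymetrix PrimeView arrays in 4 human leukemia cell lines, ALL-SIL, Jurkat, DND-41 and K562, each infected with a short hairpin RNA vector against KDM2B (shKDM2B) or a control vector (shControl). Per the labels' protocols, cells grew in medium with 10% fetal bovine serum, RNA was taken 6 days after infection, and biotinylated cRNA was hybridised. The labels give 8 groups of 2 arrays, 16 in all. Nothing in the labels says that the 2 arrays of a group came from separate infections, so p-values measure only the spread between these arrays, which may be technical. The largest correlation between 2 arrays was 0.999, and no array repeated another.

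The deposited values are log2 probe set values, made with RMA in Affymetrix Expression Console 1.3, per the submitters' processing notes. RMA corrects background, quantile-normalizes and summarises the probes of a set. Which arrays were normalized together is not given in the sources used here. From the 5th to the 95th percentile, arrays of one line differed by at most 0.143 on the log2 scale, while the mean array median was 6.59 in ALL-SIL, 4.97 in arrays labelled JURKAT, 6.76 in DND-41 and 6.59 in K562. The values therefore appear to be normalized within each line, and levels were not compared between lines except as ranks within an array. The choice of probe set per gene and the signal floor for named genes, given below, do use levels over all arrays. That floor is stricter in arrays labelled JURKAT, whose values are lower. Every test used differences within a line. Background correction could not be varied from processed values, and no slide or scan information was used here. The number of arrays limits the precision.

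Of 49395 probe sets, 102 are array controls, 44994 carry 1 gene symbol, 1832 carry several and 2569 are unnamed in the annotation table used here. For 44967 of the single-gene probe sets the gene identifier was found in a current human gene table. Each gene was represented by its single-gene probe set with the highest mean over all 16 arrays, which left 18132 genes, with no filter on dim genes. No genome coordinates were used.

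Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend in the prior variance), with one mean per group over all 16 arrays, 8 residual and 5.74 prior degrees of freedom. Tests were 2-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were shKDM2B minus shControl in each line, the mean of these differences over the 3 lines labelled as T-cell acute lymphoblastic leukemia (T-ALL), the K562 difference minus that mean, and a moderated F test of differences among the 3 lines. Overlaps of calls between lines were tested with Fisher's exact test, 1-sided. For 36 gene lists, 29 of processes or complexes and 7 of cell types, camera was run with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The lists overlap in part, as GATA1 and NFE2 stand among erythroid and megakaryocyte markers, TAL1 among erythroid markers and T-cell leukemia factors, and TCF7 and BCL11B among these factors and T-cell markers, with other genes shared too. The lists, the comparisons and the rule for named genes were fixed before the data were examined. The rule takes, per comparison and direction, the 10 genes with the largest change among those passing the test whose higher group mean lies above 6.85 (the median over genes of the mean log2 value). In single lines the values of the groups must not overlap, and in the T-ALL mean the sign must be the same in all 3 lines. Up to 2 rising and 2 falling members are named per list, KDM2B and its list are always given, and up to 2 members with the smallest p may be given as values where none passed.

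Alternatives were quantile normalization of the deposited values over all 16 arrays, a filter at the 40th percentile of mean signal, the mean of all probe sets of a gene, the replicate number as a block, limma without the trend, array quality weights, fits on the 4 arrays of one line, the cell line as the replicate, each T-ALL line in the place of K562, and each array left out in turn. Fits without the arrays labelled JURKAT, with a spread estimated without K562, with the 3' minus 5' difference of ACTB as a covariate, and with crossed replicate numbers were added after seeing the data. The procedure was tested on simulated log2 values for all 18132 genes, built from the control means and spread of each line, with 200 genes changed. For a log2 change of 1, 99 of 100 changed genes were recovered in ALL-SIL, 99 in arrays labelled JURKAT, 99 in DND-41 and 97 in K562, and for a change of 0.5 the numbers were 62, 57, 62 and 79 of 100. False calls made up 13.9% of simulated calls in ALL-SIL, 9.83% in arrays labelled JURKAT, 3.59% in DND-41 and 86.0% in K562, where a spread pooled over lines is smaller than the line's own. In the simulated T-ALL mean 2.51% of calls were false, and 490 of 18132 genes were called for the difference between K562 and T-ALL although none was simulated. Figures were drawn with matplotlib 3.10.9.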

Results

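The series measured messenger RNA in 4 human leukemia lines 6 days after infection with a hairpin against KDM2B, in order to find the genes whose expression depends on this protein. KDM2B is a histone demethylase that binds unmethylated CpG islands and belongs to a variant form of Polycomb repressive complex 1. ALL-SIL, Jurkat and DND-41 are established T-ALL lines, and K562 is a chronic myeloid leukemia line with erythroid features. Each line had 2 control and 2 knockdown arrays, and 18132 genes were tested. All values are log2, differences are shKDM2B minus shControl with the standard error of the limma fit, and n is 2 arrays per group unless stated otherwise. Rankings of named genes, such as the largest rises and falls, hold among genes that meet the naming rule.

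Lineage genes were examined first. The arrays labelled JURKAT carried high levels of erythroid transcripts and low levels of most T-cell transcripts, in control and knockdown arrays alike. In their control arrays the embryonic globin gene HBE1 measured 14.41 ± 0.00 (SD, n = 2), the erythroid transcription factor gene GATA1 9.85 ± 0.05 and KLF1 10.71 ± 0.02. The T-cell receptor signalling gene CD247 measured 3.15 ± 0.09 there, at percentile 8.02 of all genes, against percentile 78.3 in ALL-SIL and 90.5 in DND-41 control arrays. LCK, the kinase of the same pathway, stood at percentile 25.2 in arrays labelled JURKAT, 85.8 in ALL-SIL and 91.6 in DND-41. The T-cell receptor subunit gene CD3D stood higher in arrays labelled JURKAT, at percentile 65.0 in control and 84.2 in knockdown arrays (7.16 and 9.02). In those knockdown arrays it was the 1 T-cell marker above percentile 75. Of 24 measured T-cell markers, 0 lay above percentile 75 of all genes in the JURKAT-labelled controls, 8 in ALL-SIL, 15 in DND-41 and 1 in K562. Of 21 erythroid markers the numbers were 15, 1, 1 and 13 in the same order. Across probe sets, which are not independent, arrays labelled JURKAT correlated at 0.926 to 0.962 with K562 arrays, 0.837 to 0.853 with ALL-SIL and 0.815 to 0.830 with DND-41. These arrays are therefore called "labelled JURKAT", and the gene counts of the T-ALL mean are also given without them.

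**Figure D1:**
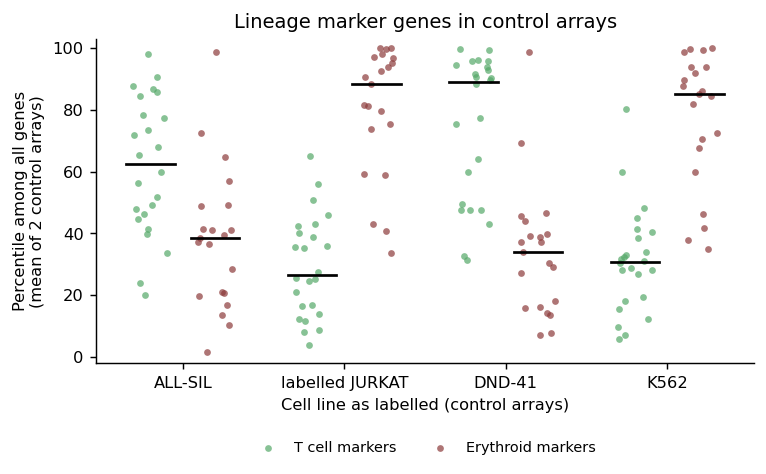
Percentile among all genes (y axis, mean of 2 arrays) of each T-cell marker (green) and erythroid marker (dark red) in the control arrays of each line as labelled (x axis). Each point is a gene and bars are medians, which for arrays labelled JURKAT are 26.6 for T-cell and 88.4 for erythroid markers.

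The targeted gene was lower in every knockdown array than in every control array of its line. KDM2B went from 11.53 ± 0.06 to 10.15 ± 0.01 (mean ± SD) in ALL-SIL, from 9.21 ± 0.14 to 7.25 ± 0.00 in arrays labelled JURKAT, from 11.18 ± 0.01 to 10.13 ± 0.02 in DND-41 and from 10.38 ± 0.04 to 9.03 ± 0.03 in K562. These differences left 38.5%, 25.6%, 48.3% and 39.2% of the control level, with log2 differences of -1.38 ± 0.07, -1.97 ± 0.07, -1.05 ± 0.07 and -1.35 ± 0.07. The limma adjusted p was 4.27e-08, 6.89e-10, 1.29e-05 and 7.67e-08. Of 4 other KDM2B probe sets, not tested singly, 3 were lower in each line, with differences from -1.98 to -0.59, and 1 differed by -0.01, -0.30, -0.42 and 0.02 in the same order. The mean of all 5 differed by -0.91, -1.35, -0.70 and -0.98. The K562 fall and the mean T-ALL fall differed by 0.11 ± 0.09, which did not pass (limma adjusted p = 0.520). Among the 9 measured subunits of the KDM2B complex, YAF2 also fell in ALL-SIL (-0.33 ± 0.07). USP7, a deubiquitinase of the complex, fell in arrays labelled JURKAT (-0.70 ± 0.07) and in K562 (-0.32 ± 0.07), where SKP1 rose (0.43 ± 0.08 and 0.29 ± 0.08, the latter -0.00182 with all its probe sets averaged), and in DND-41 no subunit passed besides KDM2B. On the K562 arrays alone USP7 and SKP1 did not pass. The calls above use the spread pooled over lines, and on the DND-41 arrays alone 1 of the 9 subunits was higher and 3, KDM2B included, were lower. As a list the subunits did not pass in any line (camera adjusted p = 0.0961, 0.498, 0.702 and 0.372).

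**Figure D2:**
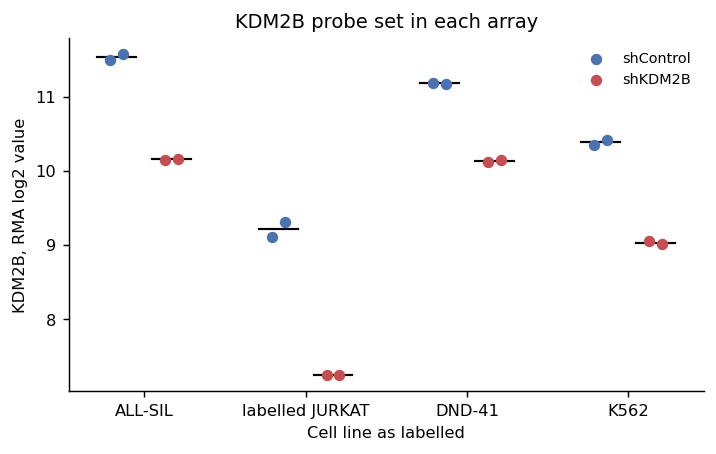
RMA log2 value of the KDM2B probe set (y axis) in each array (points) by line as labelled (x axis), control in blue and knockdown in red, with bars at the mean of 2 arrays. Knockdown means lie between 7.25 and 10.15, below both control arrays of the line, and levels cannot be compared between lines.

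In ALL-SIL cells the largest fall was in ALDH1A1, a retinaldehyde dehydrogenase, which measured 13.2-fold lower (-3.72 ± 0.14). SQOR, which oxidises sulfide in mitochondria, fell by 2.54 ± 0.11, the lymphocyte surface glycoprotein gene CD52 by 2.52 ± 0.19 and the glycolytic aldolase ALDOC by 1.82 ± 0.07. PON1 rose 6.60-fold (2.72 ± 0.14), CYP4Z1, a cytochrome P450 gene, by 2.70 ± 0.12, and the mast cell chymase CMA1 by 2.53 ± 0.12. ADAMTS17 (2.32), the cytokine IL26 (2.32), the myeloid nuclear antigen MNDA (2.27), RNASE2 (2.0), CXCL3 (1.87), RUBCNL (1.82) and NDST3 (1.73) completed the 10 largest rises. ZG16B (-2.20), LRIG1 (-1.74), the matricellular protein gene SPARC (-1.72), RHEX (-1.70), ACSM3 (-1.68) and the Mediator subunit MED21 (-1.65) completed the falls. In all, 2379 genes passed in ALL-SIL, 945 higher and 1434 lower, of which 40 and 91 changed at least 2-fold.

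Ribosomal protein genes fell as a group in ALL-SIL. Of this list 1 of 44 measured genes rose and 22 fell (1 and 27 adjusted over the list alone), with a median of -0.15 and RPL13 at -0.38. Ribosomal proteins had a camera adjusted p of 2.93e-14, and adjusted p = 0.0700 with an estimated correlation. In the glycolysis and hypoxia list 1 of 30 measured genes rose and 14 fell (1 and 14 adjusted over the list alone), PDK1, which inhibits pyruvate dehydrogenase, among the falls (-1.34). Glycolysis and hypoxia genes had a camera adjusted p of 3.24e-07, and adjusted p = 0.0700 with an estimated correlation. Among cytosolic heat shock genes 6 of 13 measured genes rose and 0 fell (6 and 0 adjusted over the list alone), with HSPH1 at 0.47 and HSPA8 at 0.31. Heat shock genes had a camera adjusted p of 0.00520, and adjusted p = 0.0700 with an estimated correlation. MYC targets and ribosome biogenesis genes were shifted upward, although 4 of 32 measured genes rose and 1 fell (4 and 1 adjusted over the list alone), with UTP20 at 0.72. MYC targets had a camera adjusted p of 0.0211, and adjusted p = 0.291 with an estimated correlation. T-cell markers shifted upward too: 6 of 24 measured genes rose and 1 fell (6 and 2 adjusted over the list alone), and the recombinase RAG1 (1.44) and the costimulatory receptor CD28 (1.22) rose most. T-cell markers had a camera adjusted p of 0.0211, and adjusted p = 0.291 with an estimated correlation. Transcription factors of T-cell leukemia moved the other way, since 0 of 18 measured genes rose and 7 fell (0 and 7 adjusted over the list alone), led by ETV6 (-1.08) and HHEX (-0.70). T-cell leukemia factors had a camera adjusted p of 0.0314, and adjusted p = 0.294 with an estimated correlation. Stem and progenitor genes were shifted downward, where 1 of 20 measured genes rose and 5 fell (1 and 6 adjusted over the list alone), ALDH1A1 and the ETS factor FLI1 (-0.95) among the falls. The list had a median of -0.04 against a mean of -0.32, and its median over all single-gene probe sets was 0.01. The shift thus rests largely on a few members with large falls. Stem and progenitor genes had a camera adjusted p of 0.0497, and adjusted p = 0.30 with an estimated correlation. For mitosis genes 0 of 34 measured genes rose and 7 fell (0 and 9 adjusted over the list alone), with the kinetochore genes NUF2 (-0.62) and TTK (-0.61) lowest. Mitosis genes had a camera adjusted p of 0.0167, and adjusted p = 0.460 with an estimated correlation. After quantile normalization over all 16 arrays the preset camera adjusted p was 0.0792. Of 8 lists that passed in ALL-SIL, 0 held in camera with an estimated correlation, where 5 had an unadjusted p under 0.05, and with any 1 ALL-SIL array left out between 3 and 8 lists passed. On the 4 ALL-SIL arrays alone, genes higher and lower numbered 15 and 2 for MYC targets, 9 and 3 for T-cell markers, 2 and 9 for T-cell leukemia factors and 8 and 0 for heat shock. For ribosomal proteins, glycolysis and hypoxia, stem and progenitor and mitosis genes they numbered 1 and 28, 3 and 15, 1 and 7, and 2 and 12. On these arrays alone 4282 genes passed in all, and these included 2339 of the 2379 in the same direction, and with any 1 ALL-SIL array left out between 1132 and 1466 passed.

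In arrays labelled JURKAT, which carried erythroid transcripts, the knockdown arrays were 12.5-fold higher for the C-type lectin gene CLEC2B (3.65 ± 0.19). The lysosomal protease gene CTSS rose by 3.0 ± 0.21, the actin-binding cofilin gene CFL2 by 3.06 ± 0.10, the heparan sulfate-cleaving enzyme HPSE by 2.99 ± 0.14, and the efflux transporter ABCG2 by 2.88 ± 0.12. TRIM29 (3.09), DHRS9 (2.93), the surface protein gene CD24 (2.88), the protein C receptor PROCR (2.86) and the cobalamin-binding protein gene TCN1 (2.75) were the other 5 largest rises. Among genes that meet the naming rule the largest fall was in LSM14A, a component of cytoplasmic mRNA granules (-2.49 ± 0.11), followed by MYEOV (-2.39 ± 0.17), PREPL (-2.13 ± 0.07) and KDM2B itself. ABCA3 (-1.87), C12orf76 (-1.77), the poly(A) ribonuclease PARN (-1.73), the nuclear receptor NR2F6 (-1.71), MED21 (-1.66) and the coenzyme Q gene COQ9 (-1.62) followed. In arrays labelled JURKAT 4442 genes passed, 1978 higher and 2464 lower, and at 2-fold or more the direction leaned upward, with 361 higher and 127 lower.

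Antigen presentation genes of MHC class I rose in arrays labelled JURKAT: 8 of 14 measured genes rose and 0 fell (8 and 0 adjusted over the list alone), HLA-C by 1.63 and the peptide transporter TAP1 by 1.46. MHC class I genes had a camera adjusted p of 4.74e-06, and adjusted p = 0.0883 with an estimated correlation. Interferon-stimulated genes went the same way, where 14 of 42 measured genes rose and 0 fell (14 and 0 adjusted over the list alone), IFI35 (2.11) and RSAD2 (1.86) in front. Interferon-stimulated genes had a camera adjusted p of 4.31e-04, and adjusted p = 0.236 with an estimated correlation. Markers of monocytes and granulocytes included 8 rises and 0 falls among 26 (8 and 0 adjusted over the list alone), with the integrin gene ITGAM at 2.72 ± 0.19 and the granulocyte factor CEBPE at 2.40 ± 0.15. Monocyte and granulocyte markers had a camera adjusted p of 0.00497, and adjusted p = 0.376 with an estimated correlation. Among inhibitors of cyclin-dependent kinases 3 of 7 measured genes rose and 0 fell (4 and 0 adjusted over the list alone), CDKN1A by 1.46 and CDKN1B by 0.76. Inhibitors of these kinases had a camera adjusted p of 0.00497, and adjusted p = 0.147 with an estimated correlation. Endoplasmic reticulum chaperones rose as a list, where 8 of 19 measured genes rose and 1 fell (9 and 1 adjusted over the list alone), MANF at 1.34 and EDEM1 at -1.44, which turned to 0.0264 with all its probe sets averaged. Endoplasmic reticulum chaperones had a camera adjusted p of 1.58e-04, and adjusted p = 0.0571 with an estimated correlation. Of the replication-dependent histone genes 6 of 17 measured genes rose and 0 fell (6 and 0 adjusted over the list alone), H4C8 most (1.2). Histone genes had a camera adjusted p of 0.00112, and adjusted p = 0.0485 with an estimated correlation. JAK-STAT feedback genes were shifted upward with SOCS1 at 2.53 and STAT5A at -1.46, and 7 of 17 measured genes rose and 2 fell (7 and 2 adjusted over the list alone). JAK-STAT feedback genes had a camera adjusted p of 0.0122, and adjusted p = 0.0795 with an estimated correlation.

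In the same arrays MYC targets and ribosome biogenesis genes fell, since 0 of 32 measured genes rose and 16 fell (0 and 18 adjusted over the list alone), the nucleolar methyltransferase FBL at -1.13. MYC targets had a camera adjusted p of 4.74e-06, and adjusted p = 0.0474 with an estimated correlation. So did genes of the ATF4 and amino acid response, of which 2 of 30 measured genes rose and 17 fell (2 and 17 adjusted over the list alone), the mitochondrial folate enzyme MTHFD2 at -1.13 and the serine synthesis enzyme PSAT1 at -1.09. Amino acid response genes had a camera adjusted p of 6.2e-05, and adjusted p = 0.0362 with an estimated correlation. Among DNA replication genes 2 of 37 measured genes rose and 20 fell (2 and 23 adjusted over the list alone), with the clamp loader subunit RFC3 at -1.07. DNA replication genes had a camera adjusted p of 9.04e-04, and adjusted p = 0.0571 with an estimated correlation. For mitosis 3 of 34 measured genes rose and 15 fell (3 and 17 adjusted over the list alone), HMMR at -0.67. Mitosis genes had a camera adjusted p of 0.00584, and adjusted p = 0.395 with an estimated correlation. PRC2, the complex that methylates histone H3 on lysine 27, had SUZ12 (-0.72) and EED (-0.68) among its falls, and 0 of 11 measured genes rose and 4 fell (0 and 4 adjusted over the list alone). PRC2 subunits had a camera adjusted p of 0.0114, and adjusted p = 0.0795 with an estimated correlation. In the glycolysis and hypoxia list 5 of 30 measured genes rose and 14 fell (5 and 15 adjusted over the list alone), VEGFA at -1.38 and NDRG1 at 1.11. Glycolysis and hypoxia genes had a camera adjusted p of 0.0122, and adjusted p = 0.236 with an estimated correlation. Of the histone lysine demethylases 0 of 19 measured genes rose and 7 fell (0 and 7 adjusted over the list alone), PHF8 at -0.69. Histone lysine demethylases had a camera adjusted p of 0.0269, and adjusted p = 0.119 with an estimated correlation. On the 4 arrays labelled JURKAT alone, genes higher and lower numbered 15 and 2 for chaperones, 10 and 1 for histones, 1 and 23 for MYC targets and 0 and 8 for PRC2. In these arrays 14 lists passed and 3 of them held with an estimated correlation.

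In DND-41, 2 genes rose and 2 fell by at least 2-fold. The tubulin gene TUBB2A rose by 1.06 ± 0.07 and the T-cell adhesion receptor CD2 by 1.04 ± 0.15, and fibronectin (FN1) fell by 1.26 ± 0.10. The protease inhibitor TIMP1 (0.93), the adaptor SLA2 (0.92), ARRDC3 (0.92), the hypoxia factor EPAS1 (0.91), the complement receptor C3AR1 (0.90), PHLDA1 (0.82), the integrin ITGA1 (0.79) and the potassium channel KCNH2 (0.75) were also higher. After FN1 and KDM2B the largest falls were LSM14A (-0.68), MED21 (-0.63), the E2F partner TFDP1 (-0.61), SNORD15B (-0.58), TNFRSF4 (-0.54), EFCAB14 (-0.53, but 0.0454 with all its probe sets averaged), MUL1 (-0.52) and the kinesin KIF23 (-0.52). With the spread pooled over all lines 183 genes passed, 131 higher and 52 lower. DND-41 arrays varied less than the pooled spread, with a median SD within groups of 0.0587 against 0.140 in K562, and on its own 4 arrays 4682 genes passed, including all 183. Quantile normalization over all 16 arrays turned the split to 100 higher and 119 lower, array weights gave 1870 higher and 2913 lower, and with any 1 DND-41 array left out between 15 and 33 genes passed.

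Mitosis genes fell as a group in DND-41: 0 of 34 measured genes rose and 10 fell (0 and 22 adjusted over the list alone), and 30 of 34 fell in the fit of the line's own arrays, with a median of -0.27. Mitosis genes had a camera adjusted p of 2.77e-16, and adjusted p = 0.0307 with an estimated correlation. KIF23 and CENPE (-0.49) had the largest falls among them. Amino acid response genes were higher as a list, where 3 of 30 measured genes rose and 0 fell (10 and 0 adjusted over the list alone), SLC7A11, the cystine transporter, at 0.64. Amino acid response genes had a camera adjusted p of 4.94e-09, and adjusted p = 0.00414 with an estimated correlation. Of endoplasmic reticulum chaperones 1 of 19 measured genes rose and 0 fell (6 and 1 adjusted over the list alone), SDF2L1 at 0.44. Endoplasmic reticulum chaperones had a camera adjusted p of 1.9e-06, and adjusted p = 0.0239 with an estimated correlation. Of interferon-stimulated genes 1 of 42 measured genes rose and 0 fell (10 and 1 adjusted over the list alone), BST2 at 0.37. Interferon-stimulated genes had a camera adjusted p of 4.36e-06, and adjusted p = 0.159 with an estimated correlation. For replication-dependent histones 2 of 17 measured genes rose and 0 fell (2 and 0 adjusted over the list alone), H1-2 at 0.42. Histone genes had a camera adjusted p of 2.37e-04, and adjusted p = 0.0239 with an estimated correlation. T-cell markers shifted upward with CD2 and CD28 (0.45), and 2 of 24 measured genes rose and 0 fell (4 and 0 adjusted over the list alone). T-cell markers had a camera adjusted p of 0.0442, and adjusted p = 0.308 with an estimated correlation. After quantile normalization the preset camera adjusted p was 0.0854. DNA replication genes were shifted upward with a median of 0.10 although 0 of 37 measured genes rose and 0 fell (3 and 0 adjusted over the list alone). DNA replication genes had a camera adjusted p of 4.18e-05, and adjusted p = 0.0239 with an estimated correlation. At an unadjusted p under 0.05 limma had 6 higher and 0 lower. Targets of p53, cholesterol biosynthesis, oxidative phosphorylation and MHC class I genes were also shifted upward, with medians of 0.15, 0.09, 0.05 and 0.18 and 0 members passing singly in limma over all genes. At an unadjusted p under 0.05 there were 5 higher and 1 lower for p53 targets, 3 higher and 0 lower for cholesterol biosynthesis, 2 higher and 0 lower for oxidative phosphorylation and 2 higher and 1 lower for MHC class I. The camera adjusted p of these lists was 1.08e-04, 3.18e-04, 0.00200 and 0.00835, and adjusted p = 0.0504, 0.0476, 0.477 and 0.354 with an estimated correlation. Adjusted over the list alone, 3 p53 targets rose and 0 genes of each of the other 3 lists did. Many more members passed on the DND-41 arrays alone, which vary less. There, genes higher and lower numbered 13 and 2 for p53 targets, 9 and 0 for cholesterol biosynthesis, 18 and 1 for oxidative phosphorylation, 11 and 1 for MHC class I and 18 and 1 for DNA replication. They numbered 23 and 2 for interferon-stimulated genes, 19 and 1 for amino acid response, 15 and 1 for chaperones, 6 and 0 for histones and 11 and 3 for T-cell markers.

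In K562 cells the carboxypeptidase-like gene CPXM1 was 10.6-fold higher after the knockdown (3.41 ± 0.14), followed by the interferon-induced GTPase GBP2 (3.26 ± 0.17), phospholamban (PLN, 3.25 ± 0.17) and the integrin ITGAM (3.15 ± 0.19). The Fc receptor FCGR2B (2.89), coagulation factor VIII (F8, 2.81), STAP1 (2.67), the T-cell receptor subunit CD3D (2.62), PAM (2.35) and FAM47E (2.33) also rose. LSM14A had the largest fall (-1.61 ± 0.11), and TFDP1 (-1.36), KDM2B, the nuclear lamin LMNB1 (-1.27), MED21 (-1.25), C12orf76 (-1.22), the phosphatase PTPN11 (-1.17), the metallothionein MT1G (-1.10), cyclin D2 (CCND2, -1.10) and GEMIN5 (-1.10) were lower too. Of these 20 genes, PTPN11 and MT1G did not pass on the K562 arrays alone. In K562 3277 genes passed with the pooled spread, 2329 higher and 948 lower, and 290 of 306 changes of at least 2-fold were rises. K562 arrays varied most, with ACTB 3' minus 5' differences of 1.46 and 4.91 in the controls and 5.59 and 2.69 in the knockdown arrays against at most 0.63 elsewhere. The K562 arrays alone gave 199 genes, 184 higher and 15 lower. Of the 306 genes with 2-fold changes, 174 (56.9%) passed there in the same direction. In data simulated with the spread of K562, 1077 of 1253 calls with the pooled spread were false. That simulation changed far fewer genes than the 3277 called here, so its false share does not give the share in these data. With the ACTB difference as a covariate 5650 genes passed in K562, and with crossed replicate numbers 5551, both fits added after seeing the data.

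**Figure D3:**
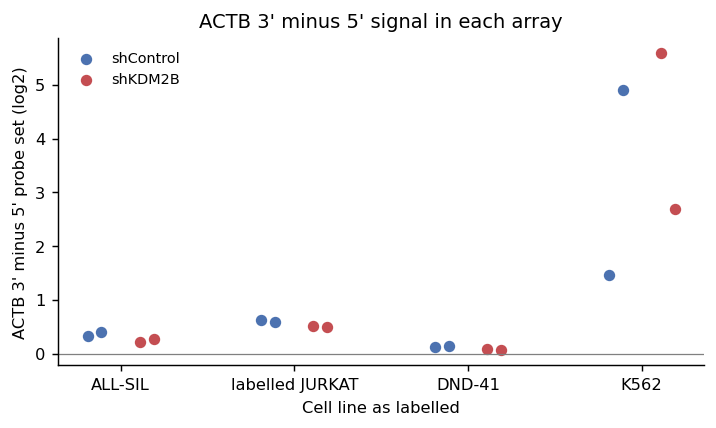
Difference between the 3' and 5' ACTB probe sets (y axis, log2) in each array (points) by line as labelled (x axis), control in blue and knockdown in red. The 4 K562 arrays lie between 1.46 and 5.59, all above the arrays of the other lines.

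The list counts for K562 use the pooled spread too. Most calls in the simulated K562 data were false with it, but far fewer genes were changed there than the 3277 called in K562. The simulated share therefore cannot be carried over to these counts, and their false share is not known. Of the K562 calls, 1203 rises and 684 falls were also called in arrays labelled JURKAT, where 67 of the rises and 3 of the falls went the other way. MHC class I genes were higher in K562, where 9 of 14 measured genes rose and 0 fell (10 and 0 adjusted over the list alone), the immunoproteasome subunit PSMB9 by 1.89 and HLA-C by 1.56. MHC class I genes had a camera adjusted p of 2.21e-06, and adjusted p = 0.140 with an estimated correlation. Among interferon-stimulated genes 17 of 42 measured genes rose and 0 fell (21 and 0 adjusted over the list alone), TRIM22 by 1.91 and IFI27 by 1.65. Interferon-stimulated genes had a camera adjusted p of 3.72e-06, and adjusted p = 0.174 with an estimated correlation. Monocyte and granulocyte markers shifted upward in a line with erythroid transcripts, and 7 of 26 measured genes rose and 0 fell (9 and 0 adjusted over the list alone), with ITGAM and lysozyme (LYZ, 1.47) in front. Monocyte and granulocyte markers had a camera adjusted p of 0.00798, and adjusted p = 0.419 with an estimated correlation. In the glycolysis and hypoxia list 11 of 30 measured genes rose and 1 fell (12 and 1 adjusted over the list alone), with NDRG1 at 1.34. Glycolysis and hypoxia genes had a camera adjusted p of 0.00157, and adjusted p = 0.174 with an estimated correlation. MYC targets and ribosome biogenesis genes were lower as a list: 0 of 32 measured genes rose and 16 fell (0 and 24 adjusted over the list alone), the pseudouridine synthase DKC1 at -0.63. MYC targets had a camera adjusted p of 6.94e-12, and adjusted p = 0.0106 with an estimated correlation. DNA replication genes were too, since 1 of 37 measured genes rose and 16 fell (1 and 16 adjusted over the list alone), the maintenance methylation factor UHRF1 at -0.79. DNA replication genes had a camera adjusted p of 1.28e-06, and adjusted p = 0.0171 with an estimated correlation. For mitosis 0 of 34 measured genes rose and 18 fell (0 and 21 adjusted over the list alone), with the centromeric histone CENPA at -0.69. Mitosis genes had a camera adjusted p of 2.97e-11, and adjusted p = 0.107 with an estimated correlation. Of PRC2 subunits 0 of 11 measured genes rose and 4 fell (0 and 5 adjusted over the list alone), SUZ12 at -0.67. PRC2 subunits had a camera adjusted p of 0.00157, and adjusted p = 0.0639 with an estimated correlation. In the cholesterol list 2 of 19 measured genes rose and 4 fell (3 and 8 adjusted over the list alone), HMGCS1 at -0.49. Cholesterol biosynthesis genes had a camera adjusted p of 0.0282, and adjusted p = 0.178 with an estimated correlation. On the K562 arrays alone 4 interferon-stimulated, 3 monocyte and granulocyte, 2 MHC class I and 1 glycolysis and hypoxia genes rose, and limma called 0 genes of the MYC, DNA replication, mitosis, PRC2 and cholesterol lists. Of these 5 lists 10, 6, 11, 3 and 3 genes were lower there at an unadjusted p under 0.05.

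**Figure D4:**
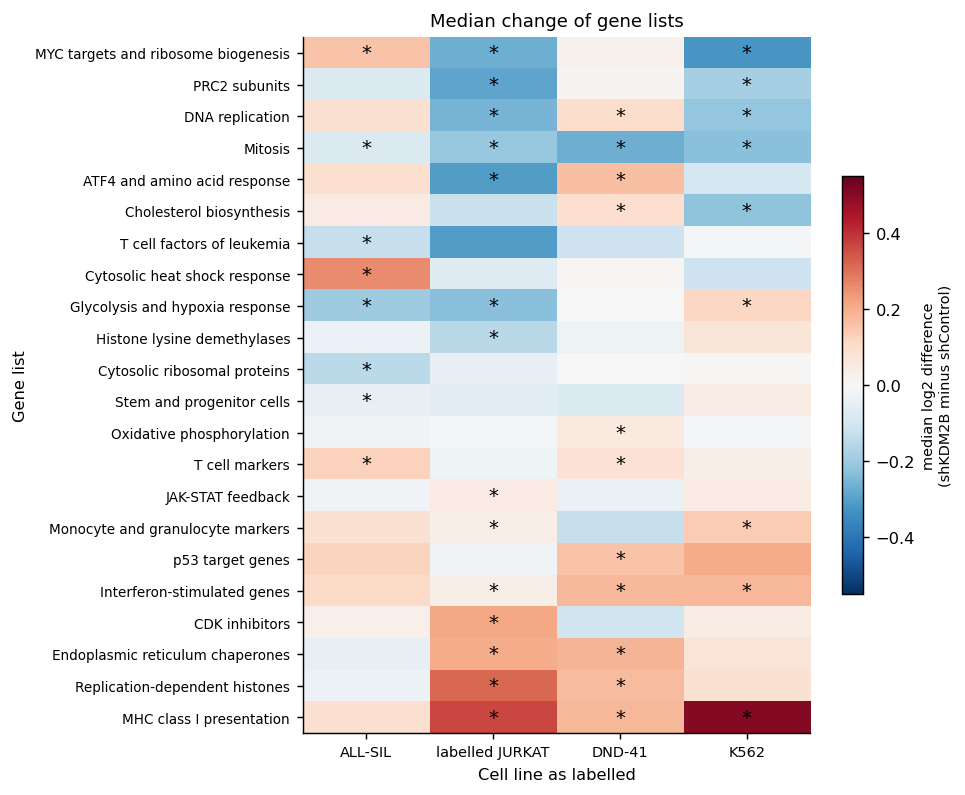
Median log2 difference (colour) of the genes of each list (rows) in each line as labelled (columns), for the 22 lists that passed camera with the preset correlation in at least 1 line, with stars where they passed. Medians run from -0.32 to 0.50, and mitosis genes are lower in all 4 columns.

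Averaged over the 3 lines labelled T-ALL, LSM14A (-1.47 ± 0.06), KDM2B (-1.46 ± 0.04), MED21 (-1.31 ± 0.05) and PREPL (-1.11 ± 0.04) fell most among genes with the same sign in each line. C12orf76 (-1.09), CCDC28A (-1.08), the DNA demethylation enzyme TET1 (-1.02), ALDOC (-0.97), PLCB1 (-0.95) and ZNF436-AS1 (-0.94) followed. CLEC2B (1.45 ± 0.11), IGSF10 (1.33 ± 0.09), EVI2B (1.24), DIPK1A (1.23), CFL2 (1.16), CTSS (1.13), NPL (1.07), the tropomyosin TPM4 (1.03), CEMIP2 (1.03) and EMILIN2 (1.01) rose most. All of these but IGSF10 rose most in arrays labelled JURKAT. In the order ALL-SIL, arrays labelled JURKAT and DND-41, CFL2 differed by 0.17, 3.06 and 0.25 and NPL by 0.48, 2.34 and 0.38. CEMIP2 differed by 0.33, 2.39 and 0.36, EMILIN2 by 0.30, 2.65 and 0.07, and IGSF10 by 2.05, 1.26 and 0.69. In the mean of ALL-SIL and DND-41, without the arrays labelled JURKAT, the differences were -0.96 ± 0.09 for LSM14A, -1.14 ± 0.06 for MED21, 1.37 ± 0.12 for IGSF10, 0.35 ± 0.14 for CLEC2B and 0.20 ± 0.16 for CTSS. CTSS had limma adjusted p = 0.552 there. In this mean 3798 genes passed, 1721 higher and 2077 lower, and 1128 passed without the arrays labelled JURKAT, 513 higher and 615 lower, 964 of them shared in direction with the 3798. With all probe sets of a gene averaged the lean turned, with 1892 higher and 1631 lower. With the 3 lines as replicates limma called 0 genes, and 1098 had an unadjusted p under 0.05.

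Mitosis genes fell in the mean of the 3 lines, where 1 of 34 measured genes rose and 21 fell (2 and 23 adjusted over the list alone), TTK at -0.48. Mitosis genes had a camera adjusted p of 4.26e-08, and adjusted p = 0.189 with an estimated correlation. Without the arrays labelled JURKAT 14 fell, with a median of -0.19. Of ribosomal proteins 0 of 44 measured genes rose and 18 fell (0 and 20 adjusted over the list alone), RPL13 at -0.43. Ribosomal proteins had a camera adjusted p of 7.54e-06, and adjusted p = 0.196 with an estimated correlation. Of these genes 10 fell without the arrays labelled JURKAT. In the glycolysis and hypoxia list 4 of 30 measured genes rose and 14 fell (4 and 16 adjusted over the list alone). Glycolysis and hypoxia genes had a camera adjusted p of 8.56e-04, and adjusted p = 0.189 with an estimated correlation. Without those arrays 0 rose and 10 fell. Neither list leaned clearly downward in DND-41. On the DND-41 arrays alone 8 glycolysis and hypoxia genes were higher and 5 lower, and 5 and 4 ribosomal protein genes. On the ALL-SIL arrays alone these numbers were 3 and 15, and 1 and 28. Interferon-stimulated genes were higher, where 12 of 42 measured genes rose and 1 fell (15 and 1 adjusted over the list alone), RSAD2 at 1.09. Interferon-stimulated genes had a camera adjusted p of 2.7e-06, and adjusted p = 0.189 with an estimated correlation. Without those arrays 8 rose and 4 fell. For MHC class I 9 of 14 measured genes rose and 0 fell (10 and 0 adjusted over the list alone), HLA-C at 0.68. MHC class I genes had a camera adjusted p of 2.47e-06, and adjusted p = 0.189 with an estimated correlation. Of MHC class I genes 0 rose singly in limma without those arrays, and 3 were higher at an unadjusted p under 0.05. T-cell markers rose as a list, where 7 of 24 measured genes rose and 0 fell (7 and 0 adjusted over the list alone), CD28 at 0.53. T-cell markers had a camera adjusted p of 0.00757, and adjusted p = 0.192 with an estimated correlation. Of T-cell markers 5 rose without those arrays. Among T-cell leukemia factors 0 of 18 measured genes rose and 6 fell (0 and 6 adjusted over the list alone), ETV6 at -0.57. T-cell leukemia factors had a camera adjusted p of 0.0104, and adjusted p = 0.220 with an estimated correlation. Of endoplasmic reticulum chaperones 7 of 19 measured genes rose and 1 fell (8 and 1 adjusted over the list alone). Endoplasmic reticulum chaperones had a camera adjusted p of 3.27e-04, and adjusted p = 0.185 with an estimated correlation. Of p53 targets 8 of 25 measured genes rose and 3 fell (8 and 3 adjusted over the list alone), TP53INP1 at 0.71 and MDM2 at -0.69. Targets of p53 had a camera adjusted p of 0.0123, and adjusted p = 0.196 with an estimated correlation. After quantile normalization the preset camera adjusted p was 0.0656. Of replication-dependent histones 5 of 17 measured genes rose and 1 fell (7 and 2 adjusted over the list alone). Histone genes had a camera adjusted p of 0.00757, and adjusted p = 0.185 with an estimated correlation. For monocyte and granulocyte markers 7 of 26 measured genes rose and 1 fell (7 and 1 adjusted over the list alone), MNDA at 1.24. Monocyte and granulocyte markers had a camera adjusted p of 0.0159, and adjusted p = 0.386 with an estimated correlation. Without the arrays labelled JURKAT the camera adjusted p was 0.0247 for T-cell leukemia factors, 0.0760 for chaperones, 0.0241 for p53 targets, 0.112 for histones and 0.993 for monocyte and granulocyte markers, of which 2 rose and 2 fell. In the mean of the 3 lines 11 lists passed, 8 of them also without those arrays, and 0 held in camera with an estimated correlation, where 8 had an unadjusted p under 0.05.

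The response of K562 was then set against the mean T-ALL response. CPXM1 (3.55 ± 0.16), F8 (3.06 ± 0.14), PLN (2.98 ± 0.19), FCGR2B (2.95 ± 0.15) and ITGAM (2.50 ± 0.22) were higher in K562 relative to the T-ALL mean. ITGAM also rose by 2.72 in arrays labelled JURKAT, so that its difference rests on ALL-SIL (-0.81) and DND-41, where it did not pass. GBP2 and PAM rose in those arrays as well (2.63 and 1.07). STAP1 (2.48), the calcium-binding protein gene SCGN (2.17), PLAAT4 (2.01), GBP2 (1.97) and PAM (1.96) followed. MNDA (-1.19 ± 0.16), CCND2 (-1.11), CMA1 (-1.11), the antiviral gene RSAD2 (-1.07), CXCL3 (-1.05), AKIRIN1 (-0.98), SYNCRIP (-0.96), ADAMTS17 (-0.95), CYP4Z1 (-0.92) and WDFY4 (-0.92) were lower. Of these, CMA1, ADAMTS17 and CYP4Z1 rose in ALL-SIL and did not pass in the other 3 lines, MNDA and RSAD2 rose in ALL-SIL and arrays labelled JURKAT and did not pass in DND-41 and K562, and CCND2 (-1.01) and CXCL3 (-0.88) fell in arrays labelled JURKAT as they did in K562, CXCL3 not on the K562 arrays alone. For this difference 1582 genes passed, 1295 higher and 287 lower in K562. The moderated F test called 4235 genes that differed among the 3 lines labelled T-ALL, and was not run without the arrays labelled JURKAT. Without the arrays labelled JURKAT 1935 genes differed between K562 and the mean of ALL-SIL and DND-41, 1454 higher and 481 lower, and 1309 of the 1582 were among them in the same direction. In simulated data without any difference 490 genes were called, without K562 control replicate 2 the number was 3831, and ALL-SIL, the arrays labelled JURKAT and DND-41 gave 3373, 2671 and 1460 genes in the place of K562.

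MYC targets and ribosome biogenesis genes responded lower in K562 than in the T-ALL mean, and 1 of 32 measured genes responded higher and 8 lower (2 and 14 adjusted over the list alone), UTP20 at -0.70. MYC targets had a camera adjusted p of 4.8e-11, and adjusted p = 0.00740 with an estimated correlation. DNA replication genes did as well, where 0 of 37 measured genes responded higher and 7 lower (0 and 9 adjusted over the list alone), UHRF1 at -0.76. DNA replication genes had a camera adjusted p of 1.42e-09, and adjusted p = 0.00740 with an estimated correlation. Glycolysis and hypoxia genes responded higher, where 17 of 30 measured genes responded higher and 0 lower (18 and 0 adjusted over the list alone), ANKRD37 at 1.32. Glycolysis and hypoxia genes had a camera adjusted p of 4.8e-11, and adjusted p = 0.0130 with an estimated correlation. Over all single-gene probe sets of this list the median knockdown difference was -0.27 in ALL-SIL and -0.25 in arrays labelled JURKAT. It was 0.03 in both DND-41 and K562, so falls in the former 2 contributed to this difference. In the cholesterol list 1 of 19 measured genes responded higher and 4 lower (1 and 5 adjusted over the list alone), DHCR7 at -0.58. Cholesterol biosynthesis genes had a camera adjusted p of 3.08e-04, and adjusted p = 0.0460 with an estimated correlation. For heat shock genes the median was -0.15 although 0 of 13 measured genes responded higher and 0 lower (0 and 0 adjusted over the list alone). Heat shock genes had a camera adjusted p of 9.5e-04, and adjusted p = 0.0333 with an estimated correlation. At an unadjusted p under 0.05 limma had 0 higher and 5 lower. Of ribosomal proteins 3 of 44 measured genes responded higher and 0 lower (3 and 0 adjusted over the list alone). Over all single-gene probe sets their median knockdown difference was -0.005 in K562, -0.14 in ALL-SIL, -0.07 in arrays labelled JURKAT and -0.003 in DND-41. Ribosomal proteins had a camera adjusted p of 0.00280, and adjusted p = 0.382 with an estimated correlation. After quantile normalization the preset camera adjusted p was 0.169. Of MHC class I genes 5 of 14 measured genes responded higher and 0 lower (6 and 0 adjusted over the list alone), PSMB9 at 1.45. MHC class I genes had a camera adjusted p of 0.00499, and adjusted p = 0.298 with an estimated correlation. For mitosis 0 of 34 measured genes responded higher and 4 lower (0 and 4 adjusted over the list alone), ANLN at -0.48. Mitosis genes had a camera adjusted p of 0.00860, and adjusted p = 0.459 with an estimated correlation. Of PRC2 subunits 0 of 11 measured genes responded higher and 3 lower (0 and 3 adjusted over the list alone), MTF2 at -0.60. PRC2 subunits had a camera adjusted p of 0.0124, and adjusted p = 0.0878 with an estimated correlation. In the order ALL-SIL, arrays labelled JURKAT, DND-41 and K562 the medians of the knockdown difference were 0.16, -0.27, 0.02 and -0.32 for MYC targets, 0.08, -0.25, 0.10 and -0.21 for DNA replication, -0.07, -0.29, 0.01 and -0.18 for PRC2, -0.08, -0.21, -0.27 and -0.23 for mitosis and 0.09, 0.37, 0.18 and 0.50 for MHC class I. By these medians arrays labelled JURKAT were lower than K562 for DNA replication and PRC2, and DND-41 for mitosis. Over all single-gene probe sets of each list these orders turned. There the medians were -0.20 in arrays labelled JURKAT and -0.27 in K562 for DNA replication, and -0.23 and -0.36 for PRC2. For mitosis they were -0.19 in DND-41 and -0.31 in K562. For MHC class I they were 0.22 in both arrays labelled JURKAT and K562. Without the arrays labelled JURKAT 9 of the 9 lists passed in the same direction, with a largest camera adjusted p of 0.0324, and 2 of them with an estimated correlation.

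Lines were last compared with one another, which share no arrays but share the standard error of each gene. Of 1978 genes higher in arrays labelled JURKAT and 2329 higher in K562, 1203 were higher in both, against 254 for independent lists, 684 were lower in both against 129, 3 were higher in arrays labelled JURKAT and lower in K562, and 67 the reverse. The immune cell genes CTSS, ITGAM and ICAM1 and the surface protein gene CD24 rose in both, and SUZ12 and USP7 fell in both, but CTSS, SUZ12 and USP7 did not pass on the K562 arrays alone. Of the 306 genes with changes of at least 2-fold in K562, 288 (94.1%) had the same sign in arrays labelled JURKAT, 151 (49.3%) in ALL-SIL and 172 (56.2%) in DND-41. ALL-SIL and DND-41, the 2 lines with T-cell transcripts, shared 26 higher genes against 6.83 for independent lists and 10 lower genes against 4.11 (Fisher's exact adjusted p = 3.84e-09 and 0.00685), and 26 genes were lower in ALL-SIL and higher in DND-41 against 10.4. ALL-SIL and K562 shared 233 higher and 237 lower genes, and 304 were lower in ALL-SIL and higher in K562 against 184 for independent lists. All 12 tests of shared direction, which treat genes as independent, passed, with 0.00685 as the largest adjusted p, but 6 of the 12 opposite overlaps also exceeded the independent number, so that passing alone does not mean a shared direction. Across all genes, which are not independent replicates, the differences in arrays labelled JURKAT and K562 had Pearson's r = 0.622 and Spearman's rho = 0.495, and ALL-SIL and DND-41 had -0.0448 and -0.0780.

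**Figure D5:**
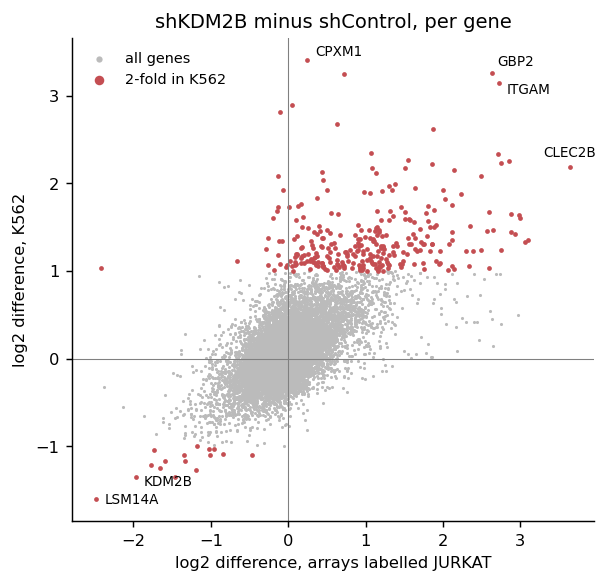
Log2 difference between knockdown and control in arrays labelled JURKAT (x axis) and in K562 (y axis), one point per gene, with the 306 genes that passed in K562 with at least a 2-fold change in red. The red points lie mostly in the upper right, where 272 of 290 rises have the same sign in both.

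In all 4 lines 9 genes were lower and 17 higher, against 0.0292 and 0.0957 for independent lists, which leaves out the shared standard error. These numbers are capped by DND-41, where 183 genes passed with the pooled spread and 4682 on its own arrays. Of 40 genes that passed in all 4 lines in any direction, independent directions would give 0.537 lower and 6.46 higher (binomial 1-sided p = 2.68e-09 and 7.03e-05, chosen after the counts were seen). The likeness of arrays labelled JURKAT and K562 alone breaks such independence. Genes named here beyond the fixed rule were chosen after their values were seen. Besides KDM2B, the lower genes were LSM14A, MED21, TFDP1, PREPL, EFCAB14, SHCBP1, MRPL48 and GSTO1, of which EFCAB14 was not lower in DND-41 with all probe sets of a gene averaged. LSM14A differed by -1.24, -2.49, -0.68 and -1.61 in ALL-SIL, arrays labelled JURKAT, DND-41 and K562, MED21 by -1.65, -1.66, -0.63 and -1.25, and TFDP1 by -0.68, -1.47, -0.61 and -1.36. The higher genes included TPM4 (0.53, 1.96, 0.60 and 0.74 in the same order), SUMF1 (0.97, 1.31, 0.51 and 0.99), the AP-1 subunit JUN (1.28, 0.89, 0.58 and 0.64), TRIB1 (0.81, 0.68, 0.66 and 0.83), the cell cycle regulator RGCC (0.67, 0.55, 0.55 and 0.56) and the antiviral membrane protein gene BST2 (0.43, 0.97, 0.37 and 0.68). On the K562 arrays alone 4 of the 9 lower genes passed in the same direction, namely KDM2B, LSM14A, MED21 and TFDP1, and 1 of the 17 higher genes, GDAP1, with 9 and 13 at an unadjusted p under 0.05.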

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

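The splits of arrays were planned before their results were seen, and the tests of line identity, RNA quality, normalization and the genes lower in all 4 lines were chosen afterwards. The response to the knockdown differed between lines in a test of the difference itself for 1582 genes (K562 against the T-ALL mean) and for 4235 genes (among the 3 lines labelled T-ALL). The latter test includes the arrays labelled JURKAT, which carried erythroid transcripts, and was not run without them. Its count therefore does not show how far lines with T-cell transcripts differ. Genes with a higher response in K562, as log2 differences from the T-ALL mean, were CPXM1 (3.55), F8 (3.06), PLN (2.98), FCGR2B (2.95), ITGAM (2.50), STAP1 (2.48), SCGN (2.17), PLAAT4 (2.01), GBP2 (1.97) and PAM (1.96). Genes with a lower response were MNDA (-1.19), CCND2 (-1.11), CMA1 (-1.11), RSAD2 (-1.07), CXCL3 (-1.05), AKIRIN1 (-0.98), SYNCRIP (-0.96), ADAMTS17 (-0.95), CYP4Z1 (-0.92) and WDFY4 (-0.92). Of the latter, CMA1, ADAMTS17, CYP4Z1, MNDA and RSAD2 did not pass in K562 itself, and their difference comes from rises in other lines. The gene lists that differed had median differences of -0.27 for MYC targets, -0.20 for DNA replication genes, -0.16 for cholesterol biosynthesis, -0.15 for heat shock genes, -0.11 for PRC2 subunits, -0.0313 for mitosis genes, 0.0623 for ribosomal proteins, 0.29 for MHC class I genes and 0.33 for glycolysis and hypoxia genes. With an estimated correlation 5 of these 9 lists passed, and PRC2 subunits, mitosis genes, ribosomal proteins and MHC class I genes did not (camera adjusted p = 0.0878, 0.459, 0.382 and 0.298). Ribosomal proteins did not pass after quantile normalization either (camera adjusted p = 0.169). For glycolysis and hypoxia genes, falls in ALL-SIL and arrays labelled JURKAT contributed to the difference. Their medians over all probe sets were -0.27 and -0.25, against 0.03 in DND-41 and in K562. The arrays were split within lines in 100 ways. As many genes as in the T-ALL mean (3798) were called by 2 splits, the labelled one included (highest other 3947). As many as in the F test (4235) were called by 3 (highest other 5142). The other splits as large for these counts kept control and knockdown arrays apart in every line and exchanged them in some lines. A chance division of these arrays thus does not account for either count. Since the splits only regroup arrays within a line, which may be technical repeats, they cannot exclude chance differences between infections or between lines. For K562 against T-ALL 9 of 100 splits, the labelled one included, called as many as 1582 (highest other 4002), so this test does not exclude chance for that count. Of these splits 3 set K562 control replicate 1 and knockdown replicate 2 against the other K562 arrays, which parts the lower from the higher ACTB 3' minus 5' values. Others, with 2143 to 2184 genes, kept control and knockdown arrays apart in K562 and in arrays labelled JURKAT but exchanged them in either of these. Such splits are not chance divisions of those arrays, so the 9 splits do not settle whether chance gave the 1582 genes. The split with 4002 genes kept control and knockdown arrays apart in every line and exchanged them in some lines.

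The arrays labelled JURKAT carried erythroid transcripts in control and knockdown arrays. An exchange of labels with the K562 arrays would put T-cell transcripts on the K562 arrays, where 1 of 24 T-cell markers lay above percentile 75 of all genes. Jurkat cells as a large part of a mixture with erythroid cells would raise T-cell markers above their level in K562, and their median percentile was 26.6 against 30.8 in K562, with CD247 and LCK at percentiles 8.02 and 25.2. Cells of another, erythroid line under this label remain a candidate explanation. Of 24 T-cell markers 0 lay above percentile 75 in its control arrays and 1 (CD3D) in its knockdown arrays. Which line it would be was not tested.

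Of the 306 genes with changes of at least 2-fold in K562, 174 (56.9%) passed on the K562 arrays alone. Nearly all of the 306 changes were rises, in arrays with unequal loss of 5' signal. That loss alone would give signs unrelated to arrays without it, yet 94.1% of these genes had the same sign in arrays labelled JURKAT, which argues against it as the whole cause. Normalization within one line stays open: 100% of these genes passed in the same direction after quantile normalization over all arrays, but arrays of one line already differed by at most 0.143 in their quantiles, so that it could move small changes, as in DND-41, and could hardly undo a 2-fold one. A response shared by 2 sets of arrays with erythroid transcripts stays open as a biological explanation, as does a shared effect of the hairpin vector, and neither was tested.

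Lower levels of the same genes in all 4 lines were the last pattern. Of 40 genes that passed in all 4 lines, 9, KDM2B included, were lower in each where independent directions would give 0.537, so the 4 lines did not move independently. Arrays labelled JURKAT and K562 alone break such independence (Pearson's r = 0.622 across all genes). The comparison therefore cannot show a direction shared by all 4 lines beyond that pair. Without the arrays labelled JURKAT, 9 genes were lower and 18 higher in ALL-SIL, DND-41 and K562. Independent lists would give 0.215 and 0.877, but these numbers leave out the shared standard error, so they do not settle it either. On the K562 arrays alone 4 of the 9 genes lower in all 4 lines passed. Whether LSM14A, MED21 and the others lie downstream of KDM2B or are further targets of the hairpin cannot be told apart, since the series has 1 knockdown label and no hairpin sequence was used here.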

How the results depend on the processing

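Fits without JURKAT-labelled arrays, with a spread without K562, with the ACTB covariate and with crossed numbers were chosen after seeing the data, and the cause of a change was not tested unless stated. KDM2B kept its direction and passed in every line under every alternative run, at -0.91, -1.35, -0.70 and -0.98 with the mean of all probe sets and from -2.07 to -1.87 in arrays labelled JURKAT and -1.06 to -1.04 in DND-41 with an array left out, and with lines as replicates its mean of -1.46 had adjusted p = 0.794 while 0 genes passed. Counts below are for ALL-SIL, arrays labelled JURKAT, DND-41, K562, the T-ALL mean, K562 against T-ALL and the F test, where given. Array weights gave 4269 (ALL-SIL), 4783 (DND-41), 1212 (K562), 6652 (T-ALL mean), 403 (K562 against T-ALL) and 8479 (F test). Fits on one line gave 4282 (ALL-SIL), 4682 (DND-41) and 199 (K562). A spread without K562 gave 5361, 7060, 3187, 6801 (T-ALL mean) and 8638 (F test). The ACTB covariate gave 5015, 6801, 2700, 5650, 6444 and 3916, without the F test. The mean of all probe sets gave 400 in DND-41. In the place of K562, ALL-SIL gave 3373, arrays labelled JURKAT 2671 and DND-41 1460. Without arrays labelled JURKAT the T-ALL mean had 1128 genes and 17 passing lists. The replicate number as a block gave 1008, 2878, 7, 1802, 2172, 450 and 1711, but same-numbered arrays deviated together with r = -0.117, 0.0401, 0.112 and -0.638, so the numbers do not pair the samples. Crossed numbers gave 1092 in ALL-SIL and 5551 in K562. With an array left out, which leaves a group of 1 assumed to vary like the others, counts ran 1132 to 1466, 3043 to 3199, 15 to 33, 2639 to 4920, 2882 to 3449, 1167 to 3831 and 2903 to 3838. Passing lists with an estimated correlation numbered 0, 3, 6, 2, 0 and 5, and with an array left out 3 to 8, 13 to 14, 10 to 11, 8 to 10, 10 to 11 and 8 to 12. Of 3823 values of named genes under an alternative, 3549 kept their direction and side of the threshold, 269 no longer passed, and 5 changed sign. With the mean of all probe sets of a gene these were EDEM1 (0.0264 in arrays labelled JURKAT), EFCAB14 (0.0454 in DND-41), SKP1 (-0.00182 in K562) and KDM2B (-0.00101 in K562 against T-ALL). Without the arrays labelled JURKAT it was KDM2B (-0.14 in K562 against T-ALL). Several alternatives leave the difference itself unchanged and alter only its error or the adjustment. These are the dim filter, replicate and crossed numbers, no trend, array weights, one-line fits, a spread without K562 and lines as replicates. A kept direction there, also for KDM2B, was fixed in advance and counts for nothing. Signal near background limits dim genes, for which arrays compress changes.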

Other observations

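The test of Polycomb target regulators here was chosen after the result was seen. Gene groups that stood in no comparison so far moved as single genes more than as lists, given here in the order ALL-SIL, arrays labelled JURKAT, DND-41 and K562. Among erythroid markers rises numbered 1, 5, 0 and 4 and falls 6, 4, 1 and 1 of 21 (7, 9, 3 and 5 changed adjusted over the list alone), and in arrays labelled JURKAT the heme synthesis enzyme ALAS2 (1.32 ± 0.19) and EPB42 (1.22 ± 0.15) rose while the anion exchanger SLC4A1 (-1.49 ± 0.12) and the globin chaperone AHSP (-1.25 ± 0.26) fell. In K562, ALAS2 (0.64 ± 0.19) and EPB42 (0.91 ± 0.15) rose and the transferrin receptor TFRC fell (-0.43 ± 0.06), and the list's camera adjusted p values were 0.141, 0.760, 0.0778 and 0.606. HOX genes and their cofactors gave camera adjusted p values of 0.421, 0.857, 0.633 and 0.784, with the cofactor PBX3 rising in ALL-SIL (0.52 ± 0.10), arrays labelled JURKAT (1.10 ± 0.10) and K562 (1.36 ± 0.10), and 20 of their 32 listed genes were measured. For immediate early and AP-1 genes, JUN rose in each line, and EGR1 fell in arrays labelled JURKAT (-1.59 ± 0.12) and K562 (-0.41 ± 0.12), with camera adjusted p values of 0.560, 0.877, 0.293 and 0.959. The cell death gene PMAIP1 rose in arrays labelled JURKAT (1.26 ± 0.19) and BIK in K562 (0.89 ± 0.18), and BCL2 family genes gave 0.939, 0.345, 0.530 and 0.836. NF-kB targets gave 0.946, 0.354, 0.860 and 0.142, with the adhesion molecule ICAM1 at 1.18 ± 0.11 in arrays labelled JURKAT and 1.45 ± 0.11 in K562. In MHC class II presentation CTSS rose in arrays labelled JURKAT and K562 (1.60 ± 0.21), HLA-DPA1 fell in ALL-SIL (-1.20 ± 0.13) and arrays labelled JURKAT (-0.71 ± 0.13), and the list gave 0.195, 0.799, 0.187 and 0.836. NOTCH targets gave 0.572, 0.857, 0.721 and 0.959, with HEY1 lower in ALL-SIL (-0.78 ± 0.16) and arrays labelled JURKAT (-1.23 ± 0.16). The remaining Polycomb complex 1 subunits gave 0.939, 0.771, 0.338 and 0.959, with CBX7 at 0.82 ± 0.11 in K562, and the megakaryocyte, B-cell, natural killer cell and fibroblast or epithelial markers passed camera in none of the 4 lines. CD24, a surface protein listed among B-cell markers, rose in arrays labelled JURKAT (2.88) and K562 (1.65), and GZMH, a granzyme of cytotoxic cells, rose in ALL-SIL (1.18 ± 0.11). On the K562 arrays alone PBX3, ICAM1 and CD24 passed, and ALAS2, EPB42, TFRC, JUN, EGR1, BIK, CTSS and CBX7 did not. With each line fitted on its own arrays, erythroid markers higher numbered 1, 9, 2 and 0 and lower 5, 6, 6 and 0, in the order above.

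A hypothesis was that lower KDM2B might raise developmental regulators that Polycomb complexes hold silent in many cell types. The list of 46 measured regulators passed camera as higher in 0 of the 4 lines (camera adjusted p = 0.281, 0.908, 0.309 and 0.436), and in 0 at an unadjusted p under 0.05. Single members changed, with GATA6 (1.26 ± 0.15) and PAX6 (0.80 ± 0.15) rising in K562, FOXA1 (0.65 ± 0.14) and PAX6 (0.62 ± 0.15) in arrays labelled JURKAT, and DLX2 falling in both (-1.34 ± 0.14 and -0.85 ± 0.14), but on the K562 arrays alone only GATA6 passed. Members went both ways, with list medians of 0.05, -0.03, -0.11 and -0.04, and arrays compress changes of dim genes, so these values leave a rise of such regulators open.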
